A study of Mus musculus with 8 samples.

How the data were processed

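Total RNA from cultured mouse CD4+ T cell lines was measured on 8 Affymetrix expression arrays, 2 for each of 4 lines. Per the labels, the lines were BDC (a pathogenic T cell line from BDC NOD mice), N79 (a neutral control line from NOD mice), N206 (a regulatory line from NOD mice) and NR206 (a regulatory line from NOR mice). The labels name Affymetrix Expression Console as the authors' processing tool. Its version, the summarization method, the normalization between arrays and a genome build are not given in the sources used here. The deposited values are probe set intensities on a linear scale, not log values, and ran from below 1 to 544162. The medians of the arrays over all rows differed between 71.1 and 102, so the deposited columns were not exactly quantile-normalized over these rows. All 8 columns were used, 0 columns were left out, and nothing states whether the 2 arrays of a line came from separate cultures.

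The table held 35557 rows. A table of probe genes for this array listed 23410 of them, 21789 with exactly 1 gene symbol and 1621 with several. The other 12147 rows, which that table does not list, served as a background level. Where several rows carried 1 symbol (999 genes), the row with the highest mean over the 8 arrays stood for the gene, which left 19938 genes. Symbols and the order of genes along the chromosomes came from the probe gene table and from a mouse gene table of the GRCm38.p6 annotation. By gene identifier 21698 rows matched the latter, 0 symbols changed, and 19855 genes could be placed in order. No reads were aligned, and no coordinates were used beyond this order.

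Intensities were log2-transformed without an offset. A single limma model of 4 group means was fitted to all 8 arrays with lmFit and eBayes (4 residual degrees of freedom, prior degrees of freedom 1.63), since groups of 2 arrays alone leave a poor estimate of the spread. All p-values of genes are two-sided p-values of this moderated test, adjusted by the Benjamini-Hochberg method over the 19938 genes, with a threshold of 0.05 on the adjusted p. A gene past it is said to have risen, fallen, or been higher or lower. The comparisons were the mean of both Treg lines minus BDC, the same mean minus N79, BDC minus N79, and NR206 minus N206. A 5th test asked which genes set both Treg lines apart from both other lines. It took the largest of the 4 single-line p-values where all 4 differences had 1 sign, and adjusted it over all genes (an intersection-union test). The same count was made for the other two ways of pairing the 4 lines.

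Gene groups were 34 lists with 772 members, of which 682 were measured. Lists share members, so their calls are not independent. Eomes, for example, is in the Tr1, CD8 T cell and natural killer cell lists, and Il12rb2 is in the Th1 and natural killer cell lists. Klrd1 is in the KIR and natural killer receptor list and the natural killer cell list, and Klrc1 and Klrk1 are in the former and the CD8 T cell list. Each list was tested with limma camera at a preset correlation between genes of 0.01, adjusted over the 34 lists within a comparison. The test was repeated with the correlation that camera estimates from the data, and that adjusted p is printed beside each list. Members were also counted after adjusting over the members of the list alone. T cell receptor segments with a row of their own numbered 9, so the arrays say little on receptor usage.

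Some intensities lay so close to 0 that a plain log2 difference exceeds any measurable one. Fold sizes in the text were therefore computed after raising values to a floor, which is the median of the rows absent from the probe gene table on each array (39.1 to 58.5). A fold is printed as "at least" where 1 side lay at or below the floor on all its arrays, and no fold is given where both sides did. Tests and log2 differences refer to the values without a floor. This floor was chosen after seeing the data, and a fit on the floored values is among the alternatives.

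Named genes followed a fixed rule. For each comparison it takes the 10 largest increases and 10 largest decreases among genes past the threshold whose arrays on 1 side all lay above those on the other, without predicted or uncharacterised symbols, and up to 4 members past the threshold from each list. For the genes set apart in both Treg lines it takes the 10 with the largest mean difference in each direction. Always named were Kir3dl1, Kir3dl2, Foxp3, Il10, Ifng, Il2ra, Ctla4, Il4, Il17a, Tgfb1, Tbx21, Gata3, Gzmb, Lag3, Cd4, Cd8a and the T cell receptor segments with the largest differences. Groups, comparisons, the tests of these comparisons, lists, this rule and the alternatives named next were all set before the data were examined.

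Between 13502 and 14531 genes per array lay above the floor, and 27.1% to 32.3% of genes lay at or below it. The correlation between the 2 arrays of a line, on log2(value + 16), was 0.976 for BDC, 0.976 for N79, 0.963 for N206 and 0.972 for NR206, and between lines it was 0.804 to 0.882. The number of arrays limits the precision: in data simulated with 200 changed genes, a 3-unit log2 difference was recovered in 66% of genes for both Treg comparisons, 54% for BDC minus N79, 50% for NR206 minus N206 and 28% for the 5th test. At a 1-unit difference 4% or less were recovered. Apart from the 5th test, the real comparisons called 1157 to 5419 genes, so the adjustment there was less strict than with 200 changed genes. Of the 5419 genes called for the Treg lines minus BDC, 3640 differed by at least 2-fold, so smaller differences were called as well. The simulated rates therefore do not give the share of real differences found.

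The alternatives set in advance were quantile normalization, centring each array on its median, leaving out the lower 40% of genes by mean, the mean of all rows of a gene, the replicate number as a block, an intensity trend with a robust prior, only the groups of a comparison in the fit, log2(value + 16), an added 2-fold threshold, and leaving out each array in turn. Rows with several symbols and rows outside the probe gene table were left out of all counts of genes and lists, since they stand for no single gene. They were fitted only for a separate count, adjusted together with the genes. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.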

Results

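Gene expression was measured in 4 mouse CD4+ T cell lines grown with interleukin 2, on 2 arrays per line. Both N206, from NOD mice, and NR206, from NOR mice, are regulatory (Treg) lines, BDC is a pathogenic line from BDC NOD mice, and N79 is a neutral line from NOD mice. The title of the series names the receptor KIR3DL1 and the inhibition of type 1 diabetes by Tregs specific for an autoantigen, so Kir3dl1 is given first. Levels are the mean ± SD of the arrays of a line (n = 2) in the deposited linear intensity units. Background means the floor, 39.1 to 58.5, the median of rows absent from the probe gene table. These rows are not known to be unexpressed. In the Treg comparisons a named gene rose or fell in 4 of 4 Treg arrays against both arrays of the other line, unless stated otherwise. Counts of genes and of list members rest on the threshold alone. Against BDC 1585 of 1734 higher and 3482 of 3685 lower genes were separated in this way, and against N79 500 of 581 and 648 of 740. In the comparisons between single lines a gene said to have risen or fallen did so in 2 of 2 arrays. The number of arrays limits the precision, and since nothing states that the arrays of a line came from separate cultures, p-values may measure technical spread only.

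Kir3dl1, which encodes a killer cell immunoglobulin-like receptor that is best known from natural killer cells, was bright in both Treg lines and at background in the other two. Its level was 1588 ± 174 in N206 and 2190 ± 767 in NR206, against 29.8 ± 5.42 in BDC and 6.93 ± 9.20 in N79. The mean of the Treg lines was at least 32.7-fold above BDC (log2 difference 5.95, SE 1.31, adjusted p = 0.0265) and at least 44.0-fold above N79 (log2 difference 9.59, adjusted p = 0.0141). As a single gene named by the title, it had unadjusted limma p-values of 0.00467 and 0.000452. Each Treg line alone was past the threshold as well, N206 with an adjusted p of 0.0497 against BDC and 0.0272 against N79, and NR206 with 0.0408 and 0.0205. Between the Treg lines the log2 difference was 0.42 (adjusted p = 0.922), and BDC and N79 both lay at or below the floor. The near-identical paralog Kir3dl2 followed the same course, with 914 ± 95.5 and 1199 ± 244 in N206 and NR206 and levels of 10.02 ± 6.67 and 2.80 ± 3.77 in BDC and N79. It was at least 18.6-fold above BDC (adjusted p = 0.0234) and at least 24.96-fold above N79 (adjusted p = 0.0157). Probe sets of paralogs this close can bind both transcripts, so the arrays do not separate the share of each gene. Against N79 the Kir3dl1 call held whichever array was left out, with an adjusted p of at most 0.0429. Against BDC (Kir3dl1, Treg lines minus BDC) the adjusted p was 0.129 and 0.131 without BDC 1 and BDC 2. It was 0.0536 and 0.0511 without N206 1 and 2, and 0.0597 and 0.0533 without NR206 1 and 2. The log2 difference stayed between 5.77 and 6.14. The Kir3dl2 call against BDC ended without either BDC array or either NR206 array (highest adjusted p = 0.129).

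**Figure D1:**
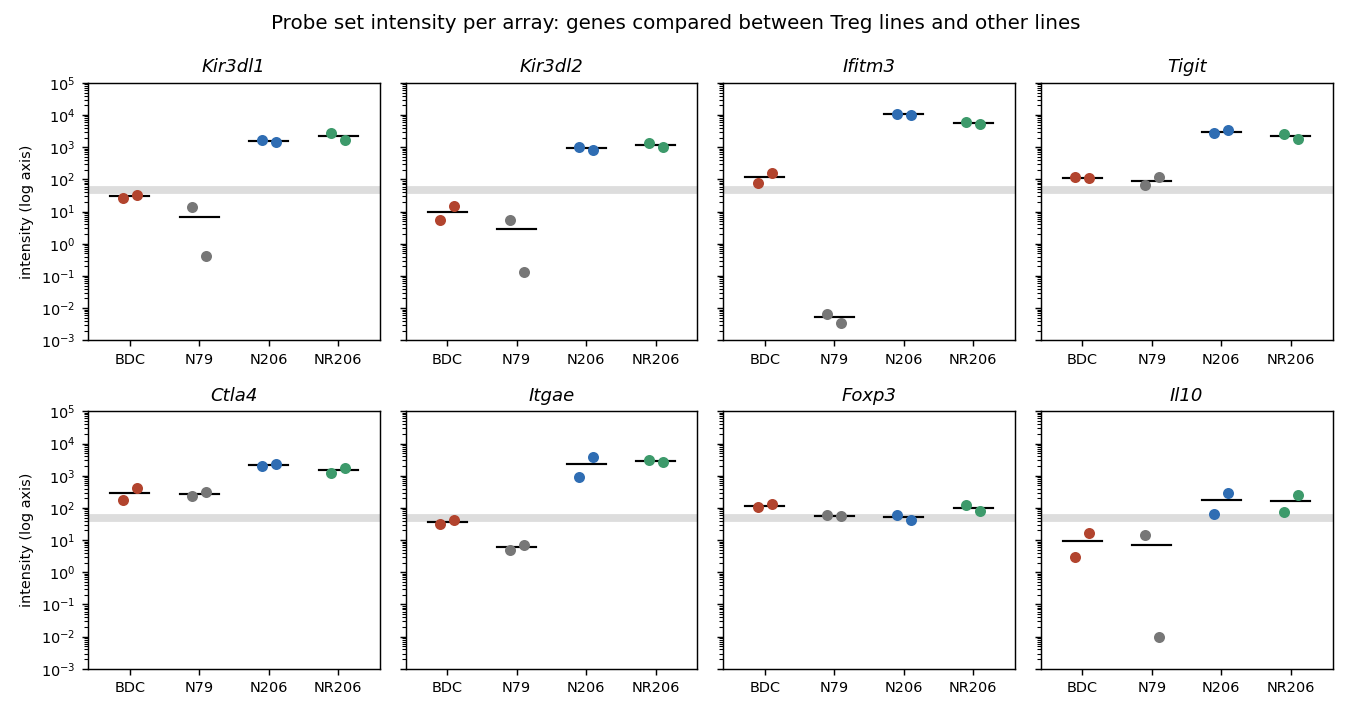
Intensity of 8 genes (log axis) in the 4 lines, with 1 dot per array, a black line at the mean of a line and a grey band for the range of the floors. Kir3dl1, Kir3dl2, Ifitm3, Tigit, Ctla4 and Itgae are brighter in N206 and NR206 than in BDC and N79, whereas Foxp3 is near the floor in all 4 lines (51.5 to 116) and Il10 varies between arrays.

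The gene of the Treg transcription factor, Foxp3, was near background in every line, with 51.5 ± 13.5 in N206, 99.0 ± 28.5 in NR206, 116 ± 17.5 in BDC and 56.8 ± 2.01 in N79. The mean of the Treg lines did not pass the threshold against BDC (log2 difference -0.71, adjusted p = 0.0931) or N79 (0.30, adjusted p = 0.614). N206 alone was lower than BDC (2.27-fold, adjusted p = 0.0452), and NR206 alone was not (adjusted p = 0.570). Over the alternatives the adjusted p of Foxp3, Treg lines minus BDC, ran from 0.0391 with floored values to 0.445. Il10, which encodes an inhibitory cytokine of Tr1 cells, read 180 ± 162 in N206, 166 ± 125 in NR206, 9.63 ± 9.34 in BDC and 7.03 ± 9.92 in N79. It was not called (adjusted p = 0.287 and 0.181). On log2(value + 16), which damps the spread of dim arrays, the adjusted p was 0.00558 and 0.00758. Over all alternatives it reached 0.605 for Il10, Treg lines minus BDC, and 0.420 for Il10, Treg lines minus N79. Ctla4, the gene of an inhibitory receptor of T cells, rose to 2150 ± 241 in N206 and 1481 ± 346 in NR206 from 296 ± 176 in BDC and 274 ± 54.9 in N79. It was 6.60-fold above BDC (adjusted p = 0.00921) and 6.53-fold above N79 (adjusted p = 0.0182). The call for Ctla4, Treg lines minus N79, ended without either N79 array (0.102 and 0.0909), without N206 2 (0.0506) and without NR206 2 (0.0500022). Tgfb1 stood between 3105 ± 608 and 3912 ± 117 in all lines and Lag3 between 99.4 ± 16.01 and 186 ± 56.5, with no call in any comparison. The Lag3 difference from BDC was close to the threshold (adjusted p = 0.0647) and ran from 0.0221 to 0.316 over the alternatives for Lag3, Treg lines minus BDC. Il17a was not called either (52.7 ± 31.6 to 90.5 ± 39.7).

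Both Treg lines differed in 1 direction from both other lines in 12 genes, 3 higher and 9 lower. Tigit, the gene of an inhibitory receptor that Tregs carry, read 3043 ± 427 in N206 and 2263 ± 563 in NR206 against 114 ± 8.22 in BDC and 92.0 ± 37.4 in N79. It was at least 19.6-fold higher in each of the 4 pairs (adjusted p = 0.0465). The interferon-induced membrane protein gene Ifitm3 reached 10486 ± 201 and 5726 ± 608 (at least 52.8-fold, adjusted p = 0.0410). The sodium, potassium and calcium exchanger gene Slc24a3 reached 410 ± 139 and 1311 ± 46.7 (at least 7.11-fold, adjusted p = 0.00243). Lower in both Treg lines was Pvr, which encodes a ligand of TIGIT and CD226 (513 ± 223 in BDC, 155 ± 15.8 in N79, below 1 in both Treg lines, at least 3.26-fold, adjusted p = 0.0123). The integrin gene Itga4 (at least 21.7-fold, adjusted p = 0.0204), S100a11 (at least 39.8-fold, adjusted p = 0.0207) and Ggh (at least 9.10-fold, adjusted p = 0.0287) were lower as well. So were Cobll1 (at least 3.38-fold, adjusted p = 0.00937) and Ivd (at least 4.81-fold, adjusted p = 0.0204). The other 3 were Zbtb16, Fsd1l and Dcbld1, which also lay at or below the floor in BDC, so that no fold against BDC is given. Among the 12, Zbtb16 and Dcbld1 were not called on log2(value + 16), where the count was 216 (88 higher, 128 lower). Kir3dl1 was outside the 12 (adjusted p = 0.770), although it had 4 of 4 Treg arrays above all 4 others, and inside the 216. The count was 3 after quantile normalization, 2 of them among the 12, and 2 with the replicate number as a block, both among the 12. It was 1 without BDC 1 or BDC 2, 3 without N79 1 and 15 without N206 1, so the 12 are not a settled list.

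Against BDC, Ifitm1, a neighbour of Ifitm3, rose 141-fold, to 15834 ± 629 in N206 and 16465 ± 2637 in NR206 from 116 ± 28.1 (adjusted p = 0.00354), and Ifitm3 rose 71.5-fold (adjusted p = 0.00126). Itgae, which encodes the integrin CD103 of tissue-resident and regulatory T cells, rose at least 41.2-fold, from 37.0 ± 7.27 to 2334 ± 2020 and 2892 ± 326 (adjusted p = 0.00316). Tigit rose 22.9-fold (adjusted p = 0.00148) and the UDP-glucose receptor gene P2ry14 45.4-fold (adjusted p = 0.00126). Ly6a2 rose at least 39.1-fold (adjusted p = 0.00307), Cyp2c55 at least 46.3-fold (adjusted p = 0.00164) and Akap14 at least 53.6-fold (adjusted p = 0.000301). The metallothionein gene Mt1 rose 39.99-fold (adjusted p = 0.00104) and the DNA replication gene Pclaf at least 55.3-fold (adjusted p = 0.00344). N79 carried both at Treg levels, Mt1 at 3432 ± 932 and Pclaf at 3657 ± 1798. The cytokine gene Il24 rose at least 21.0-fold (adjusted p = 0.00191), the hypoxia factor gene Epas1 14.4-fold (adjusted p = 0.00160) and Il10ra 5.02-fold (adjusted p = 0.00360). Il2ra, which encodes CD25, rose 2.07-fold on the mean of the lines, with 4716 ± 581 in N206, 1939 ± 88.7 in NR206 and 1488 ± 444 in BDC (adjusted p = 0.0267). The granzyme gene Gzma rose at least 29.5-fold, at 4387 ± 5429 and 1287 ± 70.2 against 26.9 ± 15.2 (adjusted p = 0.0164).

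Among the genes brighter in BDC, the potassium channel gene Kcnma1 gave the highest intensity of all genes, 543398 ± 1079.8. It read 85.9 ± 6.85 in N79, 102 ± 4.41 in N206 and 53.7 ± 12.5 in NR206 (7244-fold, adjusted p = 4.15e-05). Hspa1a, which encodes a heat shock protein, followed with 101586 ± 55497 in BDC and 55.8 ± 2.75 to 63.7 ± 0.775 elsewhere (1619-fold, adjusted p = 0.000231). Whether the intensities of Kcnma1 and Hspa1a, so high in BDC alone, are transcript levels or arise from the summarization of probes was not tested, and their folds describe the deposited values only. Zhx2 was lower in the Treg lines by at least 539-fold (adjusted p = 9.34e-05) and Kdm5b by at least 200-fold (adjusted p = 0.00587). So were Rgs16 by 178-fold (adjusted p = 0.00198), Sympk by at least 154-fold (adjusted p = 0.000656) and Ramp1 by at least 119-fold (adjusted p = 0.000207). The T cell surface gene Cd6 read 4870 ± 383 in BDC, 19.8 ± 16.6 in N206 and 14.3 ± 6.98 in NR206 (at least 109-fold lower, adjusted p = 0.00168). Cd5, whose product restrains receptor signalling, read 5981 ± 723, 3.32 ± 4.67 and 16.3 ± 3.04 (at least 134-fold lower, adjusted p = 0.0202). The lymphotoxin gene Ltb fell 89.3-fold (adjusted p = 0.00145), the early activation gene Cd69 63.6-fold (adjusted p = 0.00284), the adhesion gene Cd44 24.7-fold (adjusted p = 0.000748) and Itga4 at least 31.6-fold (adjusted p = 0.000656). Ifng, the cytokine gene of Th1 cells, fell 4.01-fold on the mean, with 17.0 ± 5.25 in N206 but 599 ± 188 in NR206 against 677 ± 362 in BDC (adjusted p = 0.0294). Only 2 of 4 Treg arrays were below both BDC arrays. Gzmb (log2 difference -0.54, adjusted p = 0.398), Tbx21 (-1.47, adjusted p = 0.0966), Gata3 (0.73, adjusted p = 0.0567), Il4 (2.18, adjusted p = 0.0602) and Cd4 (0.58, adjusted p = 0.0985) were not called. On the mean of the Treg lines, only Gzmb of these stayed uncalled under every alternative, but a mean can hide opposite changes. Gzmb differed from BDC by 0.86 in N206 (adjusted p = 0.287) and by -1.94 in NR206 (adjusted p = 0.0545, and 0.00899 on log2(value + 16)). Tbx21 differed by -4.63 in N206 (adjusted p = 0.00941) and by 1.70 in NR206 (adjusted p = 0.107, and 0.0124 on log2(value + 16)). For the mean, the adjusted p on log2(value + 16) was 0.00218 for Il4, 0.0265 for Gata3 and 0.0436 for Tbx21. Over all alternatives it ran from 0.00176 to 0.268 for Il4, Treg lines minus BDC, from 0.0181 to 0.219 for Gata3, Treg lines minus BDC, from 0.0308 to 0.422 for Tbx21, Treg lines minus BDC, and from 0.0321 to 0.322 for Cd4, Treg lines minus BDC.

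By groups, the cell cycle list had the lowest camera p and the largest share of members called. Of 48 measured members 47 rose and 1 was not called, also when adjusted over the list alone, among them Ccna2 (at least 33.1-fold, adjusted p = 0.000895), Ube2c (20.7-fold), Aurkb (17.0-fold) and Cdk1 (14.2-fold). The median log2 difference of the list was 3.13 (camera adjusted p = 1.59e-38, adjusted p = 0.337 with an estimated correlation). Of 29 early response genes 19 fell and 1 rose, with 19 lower and 2 higher when adjusted over the list alone (adjusted p = 0.00164, and adjusted p = 0.626 with an estimated correlation). Tnfaip3 fell 26.8-fold (adjusted p = 0.00140), Egr2 35.6-fold and Nr4a1 39.1-fold. Of 32 interferon-stimulated genes 16 fell and 1 rose, and 20 fell and 1 rose over the list alone (adjusted p = 0.00613, and adjusted p = 0.645 with an estimated correlation). Irf7 fell 4.79-fold and Irf9 4.29-fold, while Mx1 rose at least 6.10-fold. Of 19 Th1 genes 8 fell and 1 rose, and 10 and 1 over the list alone (adjusted p = 0.0164, and adjusted p = 0.337 with an estimated correlation). Irf1 fell 12.9-fold, Cxcr3 6.56-fold and Stat4 5.52-fold on the mean, the last below BDC only in the N206 arrays. Of 22 costimulatory genes 12 fell and 2 rose, and 16 and 2 over the list alone (adjusted p = 0.0164, and adjusted p = 0.337 with an estimated correlation). Cd226 fell 55.6-fold and Tnfrsf25 at least 61.1-fold, while Tnfrsf9 rose 7.93-fold. Of 13 Th17 genes 7 fell, also over the list alone, with Rora 18.9-fold lower (adjusted p = 0.0266, and adjusted p = 0.337 with an estimated correlation). Of 13 heat shock genes 6 fell and none rose, and 9 fell and 1 rose over the list alone, with a median log2 difference of -0.92, but the list was not called (adjusted p = 0.250).

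Of 33 genes of KIR and natural killer receptors 10 rose and 4 fell, and 11 and 4 over the list alone. Besides Kir3dl1 and Kir3dl2, Klrc2 rose at least 16.5-fold (228 ± 150 in N206, 4248 ± 103 in NR206, 23.3 ± 6.79 in BDC, adjusted p = 0.00226). The list was called as higher (adjusted p = 0.00754, and adjusted p = 0.337 with an estimated correlation) with a mean log2 difference of 1.39 but a median of -0.05. Among 14 natural killer cell markers 5 rose, and 6 over the list alone (adjusted p = 0.00613, and adjusted p = 0.337 with an estimated correlation). Eomes rose at least 5.30-fold on the mean, mostly through N206 (1505 and 1148, against 50.8 and 87.9 in NR206 and 19.2 and 36.2 in BDC). Klrd1 rose at least 8.75-fold on the mean, with only the NR206 arrays above BDC. Of 9 CD8 T cell markers 5 rose and 1 fell, and 6 and 3 over the list alone (adjusted p = 0.0103, and adjusted p = 0.337 with an estimated correlation). Cd7 was 10.6-fold higher on the mean of the lines, but only NR206 carried it (13866 ± 3921, against 42.9 ± 21.4 in N206 and 69.8 ± 49.2 in BDC). The same held for Cd8a, at least 2.99-fold higher on the mean (log2 difference 1.66, adjusted p = 0.0461), with 679 ± 144 in NR206 against 24.7 ± 16.2 in N206 and 39.6 ± 13.8 in BDC. Its adjusted p was above 0.05 in 6 of 8 fits without 1 array (highest 0.239). The B cell marker Cd79a was brighter in BDC (839 ± 353) and at least 18.0-fold lower in the Treg lines (adjusted p = 0.00153). Blk was at least 4.76-fold higher on the mean, with 21.1 ± 2.51 in N206 and 1722 ± 411 in NR206. Of 29 glycolysis and hypoxia genes 8 rose and 3 fell, and 11 and 3 over the list alone (adjusted p = 0.000372, and adjusted p = 0.603 with an estimated correlation). Slc16a3 fell at least 5.49-fold and Car12 rose at least 5.04-fold. Of 20 cholesterol synthesis genes 3 rose and 1 fell, in both counts (adjusted p = 0.0272, and adjusted p = 0.757 with an estimated correlation). Of 28 genes of receptor signalling 14 fell and 2 rose, and 18 and 5 over the list alone (adjusted p = 0.0335, and adjusted p = 0.714 with an estimated correlation). Lat fell 8.77-fold. The list of regulatory T cell genes was not called (adjusted p = 0.182): of 33 members 9 rose and 6 fell, and 9 and 9 over the list alone. Its median and mean log2 differences were -0.43 and -0.60 while the test pointed up.

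In all, 5419 of 19938 genes differed between the Treg lines and BDC, 1734 higher and 3685 lower (32.0% higher), 3640 of them by at least 2-fold. The BDC arrays were brighter, with medians over genes of 126 and 132 against 95.7 to 110 for the other 6 arrays, and the median log2 difference of all genes was -0.45. With each array centred on its median 2416 were higher and 1438 lower (62.7% higher), and after quantile normalization 2436 and 2213, so the share of higher genes rests on the scaling. On log2(value + 16) the counts were 2308 and 5439, and 5312 genes were called on both scales. The count was 1261 without BDC 1 and 1169 without BDC 2. Of 121 calls of named genes 47 and 60 ended without these arrays. Among the genes above this applied to Il2ra (highest adjusted p without 1 array 0.133), Gzma (0.102), Kdm5b (0.0529), Cd5 (0.115), Ifng (0.174), Egr2 (0.108), Nr4a1 (0.183), Cxcr3 (0.108), Stat4 (0.0959) and Cd7 (0.0725). It applied also to the lists of Th17 genes (0.0842, without N206 1), cholesterol synthesis (0.143, without BDC 2) and receptor signalling (0.118, without BDC 1). The cholesterol list lost its call after quantile normalization as well, and receptor signalling with floored values and with the replicate number as a block. Without the lower 40% of genes by mean, the calls of both these lists and of the CD8 T cell, costimulatory, KIR and natural killer receptor, natural killer cell and Th17 lists were lost.

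**Figure D2:**
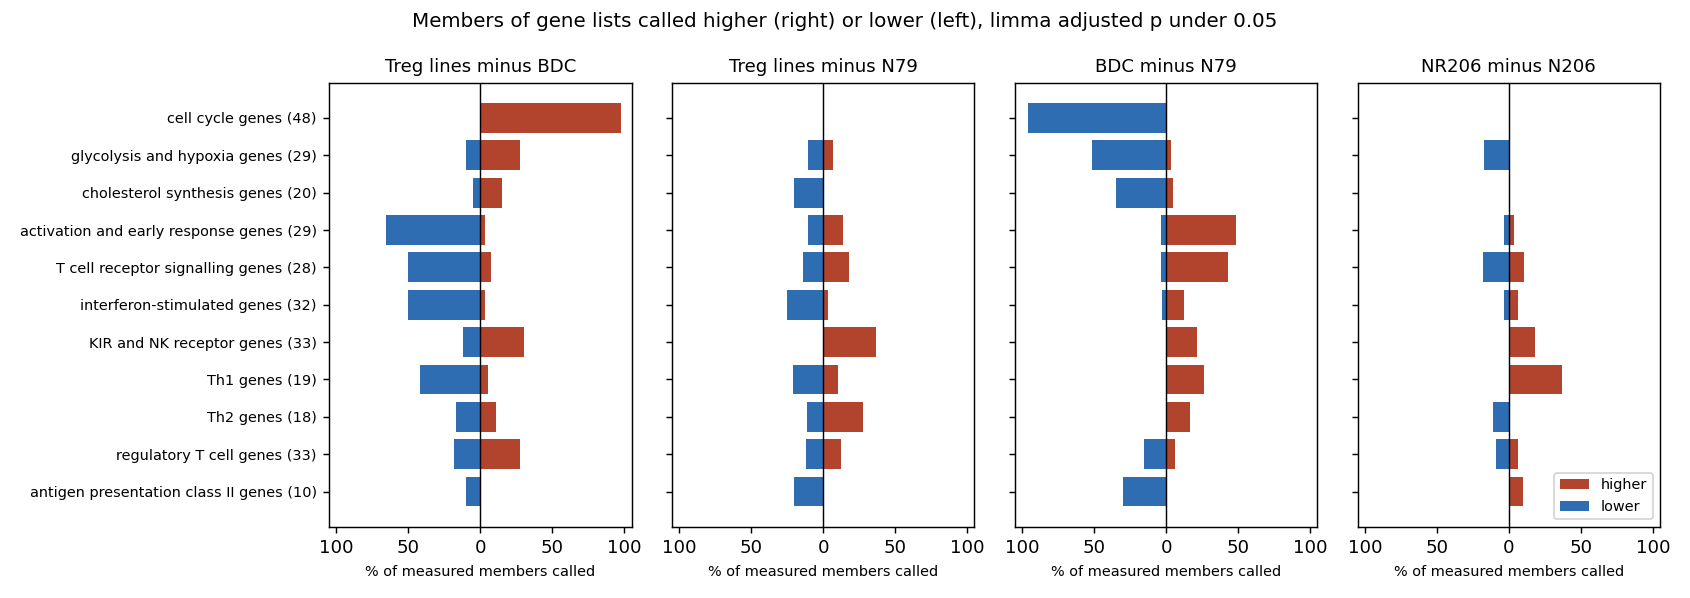
Percent of measured members called higher (right, red) or lower (left, blue) at an adjusted p under 0.05 for 11 gene lists in the 4 comparisons. Cell cycle genes are higher in the Treg lines than in BDC (47 of 48) and lower in BDC than in N79 (46 of 48), with no member called in the other two comparisons.

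Against N79, the Treg lines were brighter in Ifitm3, which was below 1 in N79 and rose at least 186-fold (adjusted p = 9.20e-05). Ifitm1 rose 157-fold (adjusted p = 0.00453). Adgrg7 went from 5.19 ± 7.32 to 6145 ± 1032 in N206 and 6264 ± 864 in NR206 (at least 148-fold, adjusted p = 0.0335). Itgae rose at least 55.4-fold (adjusted p = 0.00135), S100a4 49.8-fold (adjusted p = 0.00120) and Gpnmb at least 41.8-fold (adjusted p = 0.00235). Ly6a2 rose at least 52.5-fold (adjusted p = 0.00553), Pde3b at least 38.0-fold (adjusted p = 0.00188) and Tigit 29.5-fold (adjusted p = 0.00105). Gata3, which encodes the Th2 transcription factor, read 2528 ± 695 in N206, 1057 ± 169 in NR206 and 248 ± 7.89 in N79 (6.52-fold, adjusted p = 0.00245). Its target cytokine gene Il4 read 382 ± 60.7, 98.3 ± 41.1 and 10.3 ± 8.73 (at least 4.53-fold, adjusted p = 0.0180). Gzma rose at least 39.6-fold (adjusted p = 0.0244) and the granule gene Nkg7 at least 34.8-fold (adjusted p = 0.0258). Cd4 rose 2.13-fold (adjusted p = 0.0455), from 2138 ± 509 to 3887 ± 55.5 and 5258 ± 1090. Ifng (-2.58, adjusted p = 0.0768), Il2ra (0.23, adjusted p = 0.674), Tbx21 (-1.67, adjusted p = 0.170) and Gzmb (1.16, adjusted p = 0.257) were not called. Over the alternatives the adjusted p ran from 0.0126 to 0.253 for Ifng, Treg lines minus N79, and from 0.0484 to 0.472 for Tbx21, Treg lines minus N79.

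N79 expressed the histidine decarboxylase gene Hdc at 13513 ± 4501 against 39.7 ± 4.99 to 63.7 ± 13.8 in the other lines (285-fold lower in the Treg lines, adjusted p = 0.000223). Dcdc2a (at least 274-fold, adjusted p = 0.000104), Popdc3 (at least 179-fold, adjusted p = 0.00406), Gfra1 (at least 145-fold, adjusted p = 0.000523), Barx2 (at least 143-fold, adjusted p = 0.000167) and Igfbp7 (at least 137-fold, adjusted p = 0.000224) were lower as well. So were Inpp5j (119-fold, adjusted p = 0.00109), Ros1 (at least 104-fold, adjusted p = 0.00301), Efhd1 (at least 101-fold, adjusted p = 0.000307) and S100a11 (at least 107-fold, adjusted p = 0.000430). Ikzf2, which encodes the Treg-associated factor Helios, was brightest in N79 (898 ± 314) and lay at 7.77 ± 7.12 in N206 and 5.80 ± 4.83 in NR206 (at least 19.6-fold lower, adjusted p = 0.00626). The decoy receptor gene Il1r2 fell 20.7-fold (adjusted p = 0.00406). The T cell genes Cd6 (at least 28.2-fold, adjusted p = 0.00378), Cd44 (10.7-fold, adjusted p = 0.00140) and Fas (at least 12.8-fold, adjusted p = 0.00447) fell. Zbtb16, which encodes a factor of innate-like T cells, fell at least 14.5-fold (adjusted p = 0.000223). Cd8a read 2997 ± 227 in N79, 24.7 ± 16.2 in N206 and 679 ± 144 in NR206 (17.9-fold lower, adjusted p = 0.00443).

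By groups, 12 of 33 KIR and natural killer receptor genes rose and none fell, 17 over the list alone (camera adjusted p = 5.55e-09, adjusted p = 0.198 with an estimated correlation). Lilr4b rose 30.9-fold and Klrc2 at least 22.2-fold. Of 26 cytotoxic genes 6 rose and 1 fell, and 7 and 1 over the list alone (adjusted p = 0.0242, and adjusted p = 0.283 with an estimated correlation). Ccl5 rose 16.8-fold and Fasl at least 14.0-fold. Of 18 Th2 genes 5 rose and 2 fell, and 8 and 2 over the list alone (adjusted p = 0.00272, and adjusted p = 0.360 with an estimated correlation). Il24 rose at least 28.2-fold and Epas1 12.4-fold, and Pparg fell at least 26.5-fold. Of 17 Tr1 and interleukin 10 genes 2 rose and 1 fell, and 6 and 1 over the list alone (adjusted p = 0.00730, and adjusted p = 0.283 with an estimated correlation). Eomes rose at least 7.11-fold and Maf fell 5.94-fold. Natural killer cell markers (5 of 14 rose, 1 fell, and 6 and 1 over the list alone, with Klrd1 at least 11.7-fold higher on the mean, at 21.0 ± 4.19 in N206 and 5830 ± 1499 in NR206) had an adjusted p of 0.00272, and adjusted p = 0.351 with an estimated correlation. CD8 T cell markers (4 of 9 rose, 1 fell, and 5 and 1 over the list alone) had an adjusted p of 0.0128, and adjusted p = 0.283 with an estimated correlation. The 1 that fell was Cd8a itself, and Itgae and Eomes were among those that rose. The second CD8 chain gene Cd8b1 read 92.2 and 120 in N206, 106 and 77.6 in NR206, and 87.7 and 83.8 in N79. Of 33 chemokine genes and receptors 3 rose, with Cxcr3 at least 10.2-fold higher, and 8 rose and 2 fell over the list alone (adjusted p = 0.0282, and adjusted p = 0.584 with an estimated correlation).

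Interferon-stimulated genes were lower than in N79: of 32 members 8 fell and 1 rose, and 12 and 1 over the list alone (adjusted p = 7.70e-05, and adjusted p = 0.428 with an estimated correlation). Xaf1 fell 5.22-fold and Ifih1 4.93-fold, and Mx1 rose 4.65-fold. Of 20 cholesterol synthesis genes 4 fell, Hmgcs1 2.83-fold and Cyp51 2.78-fold, and 13 fell and 2 rose over the list alone (adjusted p = 0.000141, and adjusted p = 0.601 with an estimated correlation). Of 22 costimulatory genes 4 fell, Cd81 19.2-fold, Tnfsf9 5.02-fold and Cd40lg 4.89-fold among them, and 4 fell and 2 rose over the list alone (adjusted p = 0.00272, and adjusted p = 0.283 with an estimated correlation). Of 10 class II genes 2 fell, in both counts, with H2-Eb2 16.3-fold lower (adjusted p = 0.00272, and adjusted p = 0.360 with an estimated correlation). The macrophage marker Cybb fell at least 74.9-fold. Glycolysis and hypoxia genes were called as lower with 2 of 29 up and 3 down, and 3 and 9 over the list alone, at a median of -0.47 but a mean of 0.19 (adjusted p = 0.0238, and adjusted p = 0.615 with an estimated correlation). On log2(value + 16) this list was not called (adjusted p = 0.0757). Slc16a3 fell at least 27.0-fold. Heat shock genes had 1 of 13 lower, in both counts, Hsph1 by 2.91-fold (adjusted p = 0.0242, and adjusted p = 0.601 with an estimated correlation). None of 48 cell cycle genes was called, in both counts, and the list had a median of -0.30 (adjusted p = 0.0400, and adjusted p = 0.849 with an estimated correlation). Of 33 regulatory T cell genes 4 rose and 4 fell, and 4 and 5 over the list alone (adjusted p = 0.823). Receptor signalling genes were not called as a list (adjusted p = 0.162), with Lat at least 14.8-fold and Ubash3a at least 12.4-fold higher, nor were early response genes (adjusted p = 0.538), with Dusp6 12.8-fold higher.

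For the Treg lines minus N79, 1321 genes differed, 581 higher and 740 lower (44.0% higher), 1214 by at least 2-fold, with a median log2 difference of all genes of -0.02. The count was 2381 on log2(value + 16), of which 1287 were among the 1321. It ran from 594 without N79 2 to 1672 without N206 1, with 860 without BDC 1 or BDC 2. Of 100 calls of named genes 38 and 41 ended without N79 1 and N79 2. Among the genes above this or another array ended the calls of Adgrg7 (highest adjusted p 0.0814), Il4 (0.0706), Gzma (0.128), Nkg7 (0.0664), Cd4 (0.254), Ccl5 (0.0842), Fasl (0.0930) and Pparg (0.132). The same applied to Maf (0.0977), Xaf1 (0.180), Ifih1 (0.142), Mx1 (0.118), Hmgcs1 (0.159), Cyp51 (0.205), Cd81 (0.156) and Hsph1 (0.170). Lists whose call ended without 1 array were the cytotoxic genes (highest adjusted p 0.0913, without N206 1), chemokines (0.0913, without N206 1), glycolysis and hypoxia (0.163, without N79 1), heat shock (0.121, without N79 2) and the cell cycle (0.749, without N206 2). The calls of the cell cycle and the chemokines ended with centred arrays, and those of the CD8 T cell and the Tr1 lists without the lower 40% of genes.

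Compared with N79, in BDC the cell cycle genes Ccna2 (46.7 ± 1.41 against 2609 ± 94.4, at least 46.6-fold, adjusted p = 0.00122), Ube2c (22.9-fold, adjusted p = 0.00440) and Aurkb (22.4-fold, adjusted p = 0.00194) were lower. The early response genes Nfkbid (27.0-fold, adjusted p = 0.00184), Egr3 (25.4-fold, adjusted p = 0.00339) and Btg2 (22.5-fold, adjusted p = 0.00293) were higher. Besides Kcnma1 (6336-fold, adjusted p = 0.000101) and Hspa1a (1471-fold, adjusted p = 0.000451), whose intensities in BDC carry the doubt given above, large increases were those of Zhx2 (at least 575-fold), Rgs16 (at least 196-fold) and Tmem176b (at least 168-fold). Others were those of Sympk (at least 164-fold), Cd2 (at least 135-fold, adjusted p = 0.0441), Ramp1 (at least 127-fold) and Cxcr6 (at least 121-fold, adjusted p = 0.0158). Lat, which encodes an adaptor of T cell receptor signalling, read 5456 ± 993 in BDC and 11.3 ± 4.62 in N79 (at least 130-fold, adjusted p = 0.000411). Rora (116-fold, adjusted p = 0.00142), Bcl6 (at least 34.4-fold, adjusted p = 0.000917), Cxcr3 (at least 67.0-fold, adjusted p = 0.00198), Cd226 (at least 64.8-fold, adjusted p = 0.000259) and Tnfrsf25 (at least 65.2-fold, adjusted p = 0.00346) rose. Tnf rose 6.09-fold (10248 ± 247 against 1823 ± 991, adjusted p = 0.0262) and Gata3 3.92-fold (971 ± 2.25 against 248 ± 7.89, adjusted p = 0.00848). Lower in BDC were Dcdc2a (at least 217-fold), Hdc (208-fold), Csn2 (at least 144-fold, adjusted p = 0.00382) and Sprr1a (at least 140-fold, adjusted p = 0.00498). So were Gfra1 (at least 115-fold), Barx2 (at least 113-fold), Igfbp7 (at least 109-fold) and Cd8a (at least 53.5-fold, adjusted p = 0.00308).

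By groups, 46 of 48 cell cycle genes were lower in BDC, in both counts, at a median log2 difference of -3.28 (camera adjusted p = 4.50e-39, adjusted p = 0.525 with an estimated correlation). Of 29 early response genes 14 rose and 1 fell, and 19 and 1 over the list alone, at a median of 2.44 (adjusted p = 2.86e-05, and adjusted p = 0.525 with an estimated correlation). Of 28 receptor signalling genes 12 rose and 1 fell, and 14 and 1 over the list alone (adjusted p = 0.00892, and adjusted p = 0.525 with an estimated correlation). Ubash3a rose at least 26.7-fold and Rasgrp1 6.73-fold. Of 29 glycolysis and hypoxia genes 15 fell and 1 rose, and 20 and 4 over the list alone (adjusted p = 1.75e-07, and adjusted p = 0.525 with an estimated correlation). Tpi1 fell 6.35-fold and Slc2a3 rose at least 49.1-fold. Of 20 cholesterol synthesis genes 7 fell and 1 rose, and 13 and 1 over the list alone, with Dhcr7 4.72-fold and Fdps 4.29-fold lower (adjusted p = 1.24e-07, and adjusted p = 0.525 with an estimated correlation). Of 10 class II genes 3 fell, and 4 fell and 1 rose over the list alone, with H2-Eb2 at least 16.8-fold lower (adjusted p = 0.0237, and adjusted p = 0.525 with an estimated correlation). That call was lost with centred arrays (adjusted p = 0.0504) and without the lower 40% of genes (adjusted p = 0.265). Over all alternatives the adjusted p of the antigen presentation class II genes, BDC minus N79, ran from 0.00289 to 0.525. Of 33 KIR and natural killer receptor genes 7 rose, in both counts, with Lilr4b 99.2-fold and Lilrb4a 45.4-fold higher (adjusted p = 0.0423, and adjusted p = 0.525 with an estimated correlation). This call ended on log2(value + 16) (adjusted p = 0.0594), with floored values and after quantile normalization. The B cell marker Cd79a was at least 19.2-fold higher and the macrophage marker Cybb at least 59.5-fold lower in BDC.

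In total 3636 genes differed in the comparison BDC minus N79, 2206 higher and 1430 lower (60.7% higher), 2993 by at least 2-fold, with a median log2 difference of all genes of 0.41. With centred arrays 1035 were higher and 1740 lower (37.3% higher), and after quantile normalization 1602 and 1809, so this share rests on the scaling as well. The count was 5846 on log2(value + 16), and 3576 genes were called on both scales. It was 884 without BDC 1, 879 without BDC 2, 1854 without N79 1 and 956 without N79 2. Of 119 calls of named genes 67, 68, 48 and 65 ended without these arrays in turn. Among the genes above they were those of Cd2 (highest adjusted p 0.165), Cxcr6 (0.0855), Tnf (0.123), Gata3 (0.0574), Dhcr7 (0.0678), Fdps (0.0965) and Cybb (0.0600). The KIR and natural killer receptor list lost its call without BDC 2 (0.0962).

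Between the Treg lines, line and mouse strain cannot be told apart. Tbx21, which encodes the Th1 factor T-bet, read 1409 ± 408 in NR206 and 19.7 ± 13.6 in N206 (at least 32.98-fold, adjusted p = 0.00540). Stat4 (1642 ± 179 against 19.0 ± 16.8, at least 39.1-fold, adjusted p = 0.00504) was higher in NR206 too. So were the interleukin 12 receptor gene Il12rb2 (1336 ± 16.2 against 9.57 ± 8.97, at least 32.0-fold, adjusted p = 0.00576) and Ifng (at least 14.0-fold, adjusted p = 0.0160). Il12rb2 is on the natural killer cell list as well, and a mixture with such cells in NR206 was not tested. Higher in N206 were the Th2 chemokine receptor gene Ccr4 (1372 ± 378 against 203 ± 52.0, 6.75-fold, adjusted p = 0.00705), Epas1 (5.14-fold, adjusted p = 0.0139) and Gzmb (4701 ± 950 against 686 ± 225, 6.97-fold, adjusted p = 0.0449). Gata3 (log2 difference -1.24, adjusted p = 0.0524), Il4 (-2.02, adjusted p = 0.219) and Il2ra (-1.28, adjusted p = 0.0576) were not called. On log2(value + 16) all 3 were, with an adjusted p of 0.0105, 0.0102 and 0.0109. Over all alternatives it ran from 0.00743 to 0.236 for Gata3, NR206 minus N206, from 0.00338 to 0.476 for Il4, NR206 minus N206, and from 0.00634 to 0.179 for Il2ra, NR206 minus N206.

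**Figure D3:**
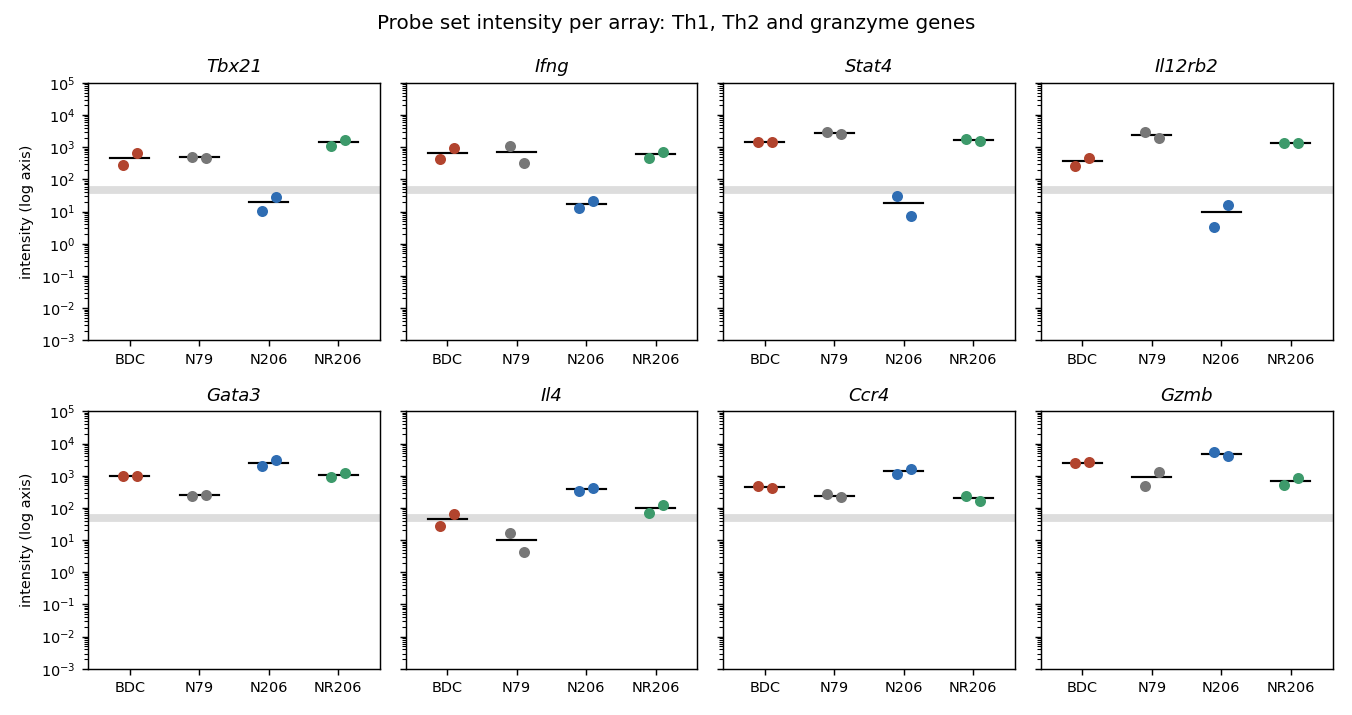
Intensity of 8 genes of T helper and cytotoxic type (log axis) in the 4 lines, with 1 dot per array, a black line at the mean of a line and a grey band for the range of the floors. Tbx21, Stat4 and Il12rb2 are at background in N206 and bright in NR206 (1409, 1642 and 1336), while Ccr4 and Gzmb are brighter in N206.

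The largest increases in NR206 were those of the placental hormone gene Prl2c5 (30196 ± 8891 against 5.76 ± 0.290, at least 706-fold, adjusted p = 0.000462) and Nyap2 (371-fold, adjusted p = 0.000176). The T and natural killer cell gene Cd7 (13866 ± 3921 against 42.9 ± 21.4, 271-fold, adjusted p = 0.00269), Mb (at least 252-fold, adjusted p = 0.000124), Greb1 (at least 187-fold, adjusted p = 0.00412) and Trpc6 (171-fold, adjusted p = 0.000788) followed. Klrd1, whose product pairs with NKG2 receptors, read 5830 ± 1499 against 21.0 ± 4.19 (at least 137-fold, adjusted p = 0.000121). Themis, a gene of T cell development, read 3733 ± 132 against 0.0201 ± 0.00674 (at least 89.3-fold, adjusted p = 1.48e-05). BDC and N79 carried Themis at 2918 ± 547 and 2549 ± 347. Rora (at least 37.7-fold, adjusted p = 0.00126), the inhibitory receptor gene Vsir (25.02-fold, adjusted p = 0.00679) and the perforin gene Prf1 (20.9-fold, adjusted p = 0.00651) were higher. Higher in N206 were the protease gene Ctsc (at least 132-fold, adjusted p = 0.000462), Cyp11a1 (at least 55.4-fold, adjusted p = 0.00402), Grm5 (at least 52.9-fold, adjusted p = 0.000699), Ifitm6 (at least 49.5-fold, adjusted p = 0.000380) and Rab27b (at least 42.0-fold, adjusted p = 8.12e-05). Entpd1, which encodes the ectonucleotidase CD39 of Tregs, read 2530 ± 452 in N206, 7.15 ± 1.63 in NR206, 112 ± 9.69 in BDC and 578 ± 127 in N79 (at least 53.1-fold, adjusted p = 0.000133). Cd44 (at least 25.1-fold, adjusted p = 0.000789), Cd28 (21.0-fold, adjusted p = 0.00312) and Eomes (19.7-fold, adjusted p = 0.00478) were also higher in N206. Cd8a was at least 16.05-fold higher in NR206 (adjusted p = 0.00686).

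By groups, 7 of 19 Th1 genes were higher in NR206 and none lower, and 9 and 1 over the list alone (camera adjusted p = 0.00485, adjusted p = 0.525 with an estimated correlation). Of 18 Th2 genes 2 were lower, and 4 lower and 1 higher over the list alone (adjusted p = 0.0160, and adjusted p = 0.525 with an estimated correlation). Of 33 KIR and natural killer receptor genes 6 were higher, and 9 over the list alone (adjusted p = 0.00961, and adjusted p = 0.525 with an estimated correlation). Klri2 was at least 119-fold and Klrc2 21.1-fold higher. Of 14 natural killer cell markers 4 were higher and 1 lower, and 5 and 2 over the list alone, but the list was not called (adjusted p = 0.645, and 0.223 on log2(value + 16)). Of 9 CD8 T cell markers 2 were higher and 1 lower, and 3 and 1 over the list alone (adjusted p = 0.645). Adjusted over all genes, the counts were 4 and 1 on log2(value + 16), where this list was called (adjusted p = 0.0402, and 0.463 with an estimated correlation). Of 29 glycolysis and hypoxia genes 5 were lower, and 11 over the list alone, with Hk2 9.65-fold and Ndrg1 5.71-fold lower (adjusted p = 5.47e-06, and adjusted p = 0.525 with an estimated correlation). Of 30 genes of amino acid stress 3 were lower and 1 higher, and 6 and 2 over the list alone, with Asns 4.15-fold lower (adjusted p = 0.00961, and adjusted p = 0.525 with an estimated correlation). Of 10 class II genes 1, H2-DMa (3.54-fold), was higher, and 6 over the list alone (adjusted p = 0.0160, and adjusted p = 0.525 with an estimated correlation). No single member was called among 20 cholesterol synthesis genes, with 1 higher and 4 lower over the list alone (adjusted p = 0.0185, and adjusted p = 0.742 with an estimated correlation). The same held for 15 fibroblast markers, with none over the list alone (adjusted p = 0.0273, and adjusted p = 0.525 with an estimated correlation). Of 33 regulatory T cell genes 2 were higher and 3 lower, and 3 and 8 over the list alone (adjusted p = 0.0462, and adjusted p = 0.578 with an estimated correlation). Entpd1 and Tnfrsf4 (7.61-fold) were among the lower. The B cell transcription factor gene Ebf1 was at least 21.1-fold higher in NR206 (887 ± 150), at a level like that of N79 (812 ± 533), and Blk at least 40.6-fold higher.

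The comparison NR206 minus N206 gave 1157 genes, 696 higher and 461 lower in NR206, 1115 by at least 2-fold, with a median log2 difference of all genes of 0.05. The count was 2271 on log2(value + 16), of which 1110 were among the 1157. It ran from 690 without BDC 1 or BDC 2 to 1445 without N206 1, with 734 without NR206 2. With only these lines in the fit it was 318, and the calls of Tbx21, NR206 minus N206 (adjusted p = 0.0555), and Cd8a, NR206 minus N206 (adjusted p = 0.0727), ended. Of 81 calls of named genes 25 and 28 ended without N206 1 and 2, and 22 and 24 without NR206 1 and 2. Among the genes above this applied to Ifng (highest adjusted p 0.0793), Epas1 (0.0614), Gzmb (0.153), Klri2 (0.111), Hk2 (0.126), H2-DMa (0.0702) and Tnfrsf4 (0.152). Of the lists, Th2 genes (highest adjusted p 0.249, without N206 2), amino acid stress (0.105, without NR206 1), KIR and natural killer receptors (0.0937, without N206 1) and class II (0.0607, without N206 1) lost their call without 1 array. So did cholesterol (0.358, without N206 1), fibroblast markers (0.284, without N206 2) and regulatory T cell genes (0.284, without N206 2). The regulatory T cell list lost its call after quantile normalization and with centred arrays as well. Class II genes and fibroblast markers lost theirs with floored values, and these lists and the KIR and natural killer receptors lost them without the lower 40% of genes.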

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

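The tests of Cd8a in this part were chosen only after its result was seen, while the differences between the Treg lines were among the comparisons set before the data were examined. A difference between the Treg lines marked 4 always named genes, since a gene that sets 1 Treg line apart from BDC or N79 need not do so in the other. NR206 minus N206 was 5.14 on the log2 scale for Ifng (adjusted p = 0.0160), 6.33 for Tbx21 (adjusted p = 0.00540), -2.80 for Gzmb (adjusted p = 0.0449) and 4.94 for Cd8a (adjusted p = 0.00686), each in 2 of 2 arrays. Over the alternatives the adjusted p ran up to 0.0793 for Ifng (without NR206 2), 0.153 for Gzmb (without NR206 1), and, with only these lines in the fit, 0.0555 for Tbx21, NR206 minus N206, and 0.0727 for Cd8a, NR206 minus N206.

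Cd8a was bright in N79 (2997 ± 227) and NR206 (679 ± 144) and at background in BDC (39.6 ± 13.8) and N206 (24.7 ± 16.2), although the labels call all cells CD4+. CD8 T cells mixed into the N79 cultures would bring the second CD8 chain, but Cd8b1 read 87.7 and 83.8 on the N79 arrays, and its log2 difference from the mean of BDC and N206 was -0.56 (SE 0.21). Other markers of these cells were dim in N79 as well, with Klrk1 at 1.01 ± 1.36 and Klrc1 at 0.394 ± 0.554, which argues against such a mixture in N79, though how this Cd8b1 probe set responds to CD8 T cells was not tested. In NR206 Cd8b1 was no brighter (106 and 77.6), but Klrk1 (2452 ± 331), Klrc1 (2459 ± 581) and Cd7 (13866 ± 3921) were bright. Itgae was bright in NR206 too (3123 and 2662), as in N206. Other markers on this list were dim in NR206: Eomes (50.8 and 87.9), Crtam (51.9 and 53.8) and Xcl1 (28.1 and 31.1). The markers thus go both ways, and a mixture with CD8 T cells or natural killer cells was not tested in NR206 and stays open. Cells that carry Cd8a beside Cd4 stay open as a candidate explanation: Cd4 in N79 differed from BDC by -0.51 on the log2 scale (SE 0.25), but bulk arrays do not resolve cells, and a difference between the lines themselves was not tested.

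Signals outside the comparisons came from probe sets that stand for no single gene, which numbered 13768. Of these 1619 differed between the Treg lines and BDC, 195 between the Treg lines and N79, 1020 between BDC and N79 and 183 between the Treg lines. Probe set 10414817 read 266876 ± 35997 in BDC against 1409 ± 351 in N79, 557 ± 303 in N206 and 971 ± 101 in NR206. Probe set 10407797 read 18633.7 ± 15791 in NR206 against 26.9 ± 0.165 in N79, 46.5 ± 9.47 in BDC and 59.7 ± 17.5 in N206. They are reported here for signals above those of the other lines, with no explanation tested.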

How the results depend on the processing

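All alternatives were planned except the floor at background, which was chosen after seeing the data. The number of genes for Treg lines minus BDC (5419) stayed within 1.5 times under every alternative except leaving out 1 array, where it ran from 1169 (without BDC 2) to 5313. For Treg lines minus N79 (1321) it was 2088 with an intensity trend and robust prior, 860 with only the groups of the comparison in the fit, 2381 on log2(value + 16) and 2634 with floored values, and 594 (without N79 2) to 1672 (without N206 1) without 1 array. For BDC minus N79 (3636) it was 5846 on log2(value + 16), 11204 with floored values (8713 higher, 2491 lower), and 879 (without BDC 2) to 3930 without 1 array. For NR206 minus N206 (1157) it was 1836 without the lower 40% of genes, 2067 with trend and robust prior, 318 with only their own arrays in the fit, 2271 on log2(value + 16), 2563 with floored values, and 690 (without BDC 1 or BDC 2) to 1445 without 1 array. Fewer arrays or fewer genes tested are part of the construction of the filter, of the smaller fits and of leaving out arrays. With floored values, the floor itself was 53.6 and 58.5 on the BDC arrays and 44.5 and 39.1 on the N79 arrays. A gene at or below it on all 4 arrays thus has a built-in BDC minus N79 difference of 0.43, which is also the median over all floored genes. For the remaining alternatives the cause was not tested.

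The 12 genes that set both Treg lines apart became 3 with quantile normalization, 75 without the lower 40% of genes, 84 with trend and robust prior, 216 on log2(value + 16) and 193 with floored values. Of the 12, 4 were shared with the 75, 5 with the 84, 10 with the 216 and 9 with the 193. Without 1 array the count ran from 1 (without BDC 1 or BDC 2) to 15. The difference Kir3dl1, Treg lines minus BDC, kept its sign throughout and ran from 5.03 with floored values and 5.34 on log2(value + 16) to 6.47 with quantile normalization. Without 1 array it was 5.77 to 6.14, but 6 of these 8 fits gave an adjusted p above 0.05 (up to 0.131). Fits without an array leave a line with 1 array, which is assumed to vary like the other groups.

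With the replicate number as a block, the counts were 4862 for Treg lines minus BDC, 1051 for Treg lines minus N79, 2932 for BDC minus N79, 899 for NR206 minus N206 and 2 for the genes that set both Treg lines apart. No label states a pairing. Deviations of replicates correlated between lines at -0.03 to 0.10 on the plain log2 scale, but at up to 0.33 for bright genes on log2(value + 16) (N79 and NR206), so a shared effect of the replicate number in part of the lines stays open. The block cost degrees of freedom, and 54 of 464 results of named genes and 1 of 42 list calls fell below the threshold with it.

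Of the 464 results of named genes, 421 stood on the same side of the threshold with quantile normalization, 417 with centred arrays, 445 on log2(value + 16), 442 with floored values, 437 with trend and robust prior, 349 with only the groups of the comparison and 464 with the mean of all rows. Without the lower 40% of genes 339 stood on the same side and 12 passed it. The filter left no value for the dim ones among the rest, and Kir3dl1 was left out of the smaller fits in this count.

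Of 42 list calls 0 held with the correlation that camera estimates, 39 held with quantile normalization, 38 with centred arrays, 40 on log2(value + 16), 38 with floored values and 29 without the lower 40% of genes. Calls held without any 1 array for 9 of 12 lists of the Treg lines minus BDC, 9 of 14 minus N79, 6 of 7 of BDC minus N79 and 2 of 9 of NR206 minus N206.

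Signs reversed in results that were not called, apart from Cd200r1, which was called between NR206 and N206 with both lines at or below the floor and had 0.18 with floored values. With centred arrays the value was -0.19 for Ifng, BDC minus N79, and with quantile normalization -0.16 for Il10, BDC minus N79. It was -0.18 with quantile normalization, -0.0515 with centred arrays and -0.0065 on log2(value + 16) for Il10, NR206 minus N206, -0.0091 with centred arrays for Lag3, NR206 minus N206, -0.0134 with quantile normalization for Tgfb1, NR206 minus N206, and 0.11 with floored values for Il17a, NR206 minus N206. Without 1 array, between BDC and N79, Ctla4 ran from -0.66 to 0.63, Ifng from -0.81 to 0.99, Il10 from -1.002 to 9.47, Il17a, BDC minus N79, from -0.0480 to 0.88, Tbx21, BDC minus N79, from -0.80 to 0.40 and Tgfb1 from -0.21 to 0.19. Between NR206 and N206, Il10 ran from -1.08 to 1.09, Il17a from -0.85 to 0.46 and Lag3 from -0.19 to 0.29. The cause was not tested.

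Signal over background limits what dim genes can show: 27.1% to 32.3% of genes lay at or below the floor, and of the called genes 272 (Treg lines minus BDC), 29 (minus N79), 157 (BDC minus N79) and 57 (NR206 minus N206) had both sides there, so that their differences are not measured.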

Other observations

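The tests on the cell cycle in this part were chosen only after the results were seen, and so was the use of the line pairings as a test, while the count over pairings itself and the test on neighbouring genes were set before. Several genes outside the groups above separated the lines by large amounts. N79 and NR206 shared bright Igf1 (8957 ± 1498 and 2940 ± 443 against 52.8 ± 41.4 in BDC and 12.9 ± 15.4 in N206), Plet1 (3116 ± 331 and 6446 ± 1439 against 21.7 ± 14.0 and 3.02 ± 3.77) and AY761185 (3003 ± 1961 and 6358 ± 653 against 4.13 ± 4.82 and 1.24 ± 1.74). NR206 alone expressed the mast cell protease gene Cma1 (2548 ± 293 against 7.72 ± 0.230 to 20.7 ± 10.4), and N206 alone the transcription factor gene Tox2 (414 ± 71.5 against 20.03 ± 5.40 to 33.4 ± 1.07). Tnfsf8 read 4116 ± 1392 in BDC, 308 ± 109 in N79, 302 ± 220 in N206 and 0.406 ± 0.562 in NR206. The X-inactivation transcript Xist read 1636 ± 67.8 in BDC, 194 ± 213 in N206, 4.59 ± 5.96 in N79 and 3.90 ± 0.986 in NR206, at least 39.2-fold higher in BDC than in N79 (adjusted p = 0.0170, above 0.05 without either BDC array, highest 0.0909).

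Among the 9 T cell receptor segments measured, Trav14-1 read 561 ± 148 in BDC and 16.5 ± 2.54 or less in the other lines (at least 12.4-fold above the Treg lines, adjusted p = 0.0344, highest without 1 array 0.155). Trbv1 read 332 ± 9.95 in BDC and 22.5 ± 11.4 to 60.4 ± 17.7 elsewhere (6.66-fold above the Treg lines, adjusted p = 0.00614, highest without 1 array 0.0529). Trav7n-5 read 115 ± 10.4 in BDC and 1.25 ± 0.178 to 5.22 ± 5.97 elsewhere (at least 2.58-fold above the Treg lines, adjusted p = 0.0116, highest without 1 array 0.0782, and at least 2.76-fold above N79, adjusted p = 0.0132, highest 0.0770). Trav7d-4 read 210 ± 12.0 in BDC, 34.8 ± 1.45 in N79, 123 ± 35.8 in N206 and 72.7 ± 29.9 in NR206 (2.29-fold above the Treg lines, adjusted p = 0.0388, and at least 5.03-fold above N79, adjusted p = 0.009999, highest without 1 array 0.0656). The gamma segment Trgv1 was bright in all lines, from 1657 ± 166 in BDC to 5343 ± 406 in NR206 (2.66-fold higher in the Treg lines than in BDC, adjusted p = 0.00419). The neurotensin gene Nts differed between the arrays of N206, at 2618 and 132417, against 22.5 ± 3.99 or less in the other lines. Genes that differed by at least 8-fold between the arrays of a line numbered 8 in BDC, 16 in N79, 18 in N206 and 8 in NR206.

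BDC combined dim cell cycle genes with bright early response genes against N79, although neither list was called with an estimated correlation (adjusted p = 0.525 for both). The BDC arrays were the brighter ones (median log2 difference of all genes 0.41), so overall brightness runs against dim cell cycle genes in BDC. The median BDC minus N79 difference of that list was -3.59 after quantile normalization (SD over members 1.54), but this test could hardly have ended otherwise. For the early response genes, which such brightness could raise, this median was not taken. Their median before that step, 2.44, lay above the 0.41 of all genes. Their list call at the preset correlation held with quantile normalization and with centred arrays, so that call did not rest on the scaling. The CD3 and CD4 genes had a median difference of 0.45 (SD 0.58), from -0.29 for Cd3d to 1.34 for Cd247, near the 0.41 of all genes. They did not fall with the cell cycle genes. This argues against other cells making up much more of the BDC cultures than of the N79 cultures. The share of T cells in either culture was not measured. A different time since the last stimulation may have contributed, and the early response list, with a median of 2.44 (SD over members 2.78), leaves this open, because the labels give no times and line and harvest cannot be told apart. A difference between the lines themselves stays open as well and was not tested.

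Genome segments that differ between NOR and NOD mice could place genes that separate NR206 from N206 next to each other. Among 1155 top genes, pairs within 10 places along the chromosomes numbered 738, against a mean of 639 in 1000 random draws matched for brightness. The ratio was 1.15 (SD over the draws 0.04). Pairs whose symbols shared their first 3 letters were not counted, so families of neighbouring genes with 1 name stem are left out. For the other pairs of NR206 with a NOD line, where segments would raise it too, the ratio was 1.06 (BDC) and 1.12 (N79). Between NOD lines it was 1.07 (N206 minus BDC), 1.10 (BDC minus N79) and 1.21 (N206 minus N79), so NR206 minus N206 exceeded 2 of these 3 but not the highest. An excess of neighbouring pairs thus also occurred between NOD lines. Before the data were examined, it was predicted that each ratio with NR206 would exceed every ratio between NOD lines if segments contributed. That prediction was not met, since all 3 ratios with NR206 lay below the 1.21 of N206 minus N79. The SD of 0.04 is a spread over random draws and not an error of a ratio, so the order of 1.15 and 1.21 stays uncertain. Thus the test gave no sign of segments, and a contribution too small for it stays open.

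The 12 genes that set both Treg lines apart from both others compare with 6 and 5 for the other two ways of pairing the lines. Of the 3 pairings 1, the real one, gave as many as 12, the highest other count was 6, and 3 pairings are too few for a share under 0.05. The 216 genes of the real pairing on log2(value + 16) compare with 125 and 92, so the real pairing was the highest on both scales.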
